A study of Arabidopsis thaliana with 6 samples.

How the data were processed

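The authors deposited counts for genes, exons, alternatively spliced parts, introns and splice junctions, with 1 column per library, and these 5 sets are the start of everything reported here. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.9 to TAIR10, and R 3.1 was used. The counting program, the use of strand and the filters before counting are not given in the sources used here. Per the labels, seedlings were grown on 0.8% agar at 22 °C after 4 days of stratification, the light was 50 µmol m-2 s-1, and libraries were made with TruSeq from 3 µg of total RNA and 12 cycles of PCR. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. No pair of libraries was close enough to be the same library counted again (chi-square per degree of freedom 2.66 or more within groups).

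Genes were tested with edgeR's quasi-likelihood F test after TMM normalization and filterByExpr, and called at an adjusted p (Benjamini-Hochberg) under 0.05. Of 33602 loci, 20151 passed the filter, and 19956 of these were found in the gene reference that gave symbols. The 15 rows of ribosomal RNA stayed in the library totals, and an alternative leaves them out. The file marks 489 loci as overlapping another, and by coordinates 4329 do.

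Usage of a part, intron or junction was tested by the same model with the log of the gene's count plus 0.5 in the same library as offset, so that a change is relative to the gene. Exons were tested on the 152631 rows that name no splicing event or the event "extreme", the other 7973 being those of the splicing set. The sources used here do not explain "extreme", and it was treated as no event. Junctions were tested where they belong to 1 gene: 4748 of 138418 hit several genes and were set aside, as were 1630 whose locus has no gene count. For a part, inclusion is the share of junction reads at its borders that enter it. Where a junction had no reads in a group, no fold is printed.

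The 18 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Named genes are the 8 that rose and the 8 that fell most with at least 10 CPM in the higher group and no overlap between groups, up to 4 of each list by adjusted p, and 10 chosen in advance. Named parts are the 6 highest and 6 lowest with at least 20 counts in the higher group and up to 5 called in the clock and splicing lists and 2 in each other list. Introns, exons and junctions are the 3 each way. Genes from the lists outside this rule, such as PAP1, SEN1, PIF4, PAR1, LNK2, PRR5, FIB2, DIN9 and CAB1 to CAB3, were named after their values were seen. Tests, lists, the naming rule and most alternatives were fixed before the data were examined.

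The methods were tested on simulated data with 200 changed features in each set. Of genes changed 2-fold 82.1% were found, of alternatively spliced parts 73.1%, of introns 52.2%, of exons 77.6% and of junctions 58.2%. For changes of 1.5-fold the shares were 64.2%, 35.8%, 5.97%, 46.3% and 26.9%, so small changes of intron usage are mostly missed. False calls numbered 17, 5, 4, 13 and 28 in the same order. For junctions they stood beside 18, 39 and 65 true calls at 1.5-fold, 2-fold and 4-fold. For genes the true calls were 43, 55 and 65, and for exons 31, 52 and 66. Among the simulated calls for genes, exons and junctions, the false share was thus above the adjusted threshold, most of all for junctions. For alternatively spliced parts and introns it was below the threshold. All 3 list tests found the 1 list that was moved and called 0 of the other 17. The simulated genes varied independently and the lists were random, so false calls for lists of co-regulated genes were not tested. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the R package data.table (1.17.8).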

Results

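The series asks how a short light signal in the middle of the night changes the transcripts of Arabidopsis thaliana Col seedlings. Plants were grown for 9 days under 12 h of light and 12 h of darkness. One group received white light for 2 h from ZT18, the other stayed in darkness, and both were harvested at ZT20, with 3 libraries in each group. Gene counts summed to between 8695843 and 12689543 per library. Libraries of one group correlated at r = 0.989 to 0.991 and libraries of different groups at r = 0.925 to 0.939 (log CPM), and the first principal component, which parts light from dark, held 82.3% of the variance. Ribosomal RNA loci took 4.77% of the counts in dark library C and 4.40% in light library A, against 0.799% to 1.75% in the other 4. This difference runs across the groups, and leaving out these 2 libraries was examined as an alternative. It leaves 2 libraries in each group, and no other pair was left out for comparison. A call lost under it cannot therefore be put down to rRNA. In what follows, changes are light relative to dark on the log2 scale with their standard error (n = 3 libraries per group), and shares are means ± SD over 3 libraries.

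The light pulse raised genes of light protection and the clock from near silence and lowered SAG21, which was abundant in the dark. ELIP1 (chromosome 3, 8084447 to 8085560) rose by 7.32 ± 0.25, from 0.507 to 83.2 CPM (adjusted p = 3.7e-12). GI rose by 6.18 ± 0.16, from 0.528 to 39.4 CPM, and LNK1 by 6.09 ± 0.12, from 1.12 to 77.1 CPM. SAG21 fell by 5.57 ± 0.17 on the log2 scale, from 3147 to 66.2 CPM, and ASN1 changed by -4.18 ± 0.26. Chalcone synthase, CHS, already present in the dark at 69.6 CPM, rose by 3.58 ± 0.09.

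Over all genes, 11353 of the 20151 tested (56.3%) changed by edgeR's quasi-likelihood test at the adjusted threshold, 5826 higher and 5527 lower in light. Without normalization beyond library totals, the same test called 4182 higher and 7397 lower, because the median change of all genes then shifted by -0.14, so the balance of rises and falls is set by the normalization. Changes of at least 2-fold were found for 1224 rising and 1085 falling genes, and of at least 8-fold for 123 and 37. In 11038 of the called genes the 3 light libraries lay apart from the 3 dark ones. Among genes with at least 10 CPM in the higher group and no overlap between light and dark libraries, those that rose most beside the genes above were AT2G22590 (7.02 ± 0.28), SAG29 (6.73 ± 0.29), BBX16 (6.23 ± 0.17), AT2G27420 (6.08 ± 0.11) and BBX31 (5.59 ± 0.23). By the same rule, those that fell most beside SAG21 and ASN1 were COR27 (-5.43 ± 0.22), FLS2 (-5.10 ± 0.23), AT3G15450 (-4.26 ± 0.11), AT1G15125 (-4.19 ± 0.23), AT4G36850 (-4.19 ± 0.14) and AT2G33830 (-4.02 ± 0.11). Of the called genes, 2078 share coordinates with another gene, among them AT3G15450, and their counts may hold reads of the neighbour. The named genes of this paragraph and the one before kept their calls under all alternatives run.

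Flavonoid synthesis answered the pulse as a whole: all 17 measured genes rose. The anthocyanin regulator PAP1 went up by 5.86 ± 0.34, F3H by 4.04 ± 0.10, FLS1 by 3.88 ± 0.09 and CHI by 3.12 ± 0.09. In the opposite direction, 16 of the 17 genes of the dark and sugar-starvation list fell, led by ASN1, SEN1 (-3.35 ± 0.22), DRM1 (-3.17 ± 0.10) and DIN10 (-2.99 ± 0.08). TPS11 (-2.71 ± 0.10) and TPS8 (-2.04 ± 0.07) fell too, and DIN9 alone rose (1.06 ± 0.17).

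Light-harvesting antenna genes rose in 17 of 20 cases, with LHCB2.2 at 3.59 ± 0.09, LHCB2.1 at 3.49 ± 0.07, LHCB2.3 at 3.36 ± 0.08 and LHCB3 at 2.81 ± 0.07. CAB1, the most abundant of them at 7665 CPM in the dark, changed by -0.19 ± 0.05 while its neighbours CAB2 (1.77 ± 0.07) and CAB3 (1.05 ± 0.07) rose. These copies and those of LHCB2 are nearly identical, and how reads were shared among them is uncertain. In the photoprotection list 7 of 11 genes rose and 0 fell, among them ELIP1, SIG5 (2.84 ± 0.08), ZEP (2.12 ± 0.07) and PSBS (1.90 ± 0.07). All 18 ribosome biogenesis genes rose, each by a moderate amount: FIB2 by 1.47 ± 0.10, AT5G27120 by 1.33 ± 0.08, NOP56 by 1.28 ± 0.07, CBF5 by 1.15 ± 0.07 and NUC1 by 1.04 ± 0.07. Heat-shock genes rose in 3 of 6 cases, HSP70 by 4.31 ± 0.08, HSFA2 by 3.41 ± 0.31 and HSP101 by 1.06 ± 0.10. Light-signalling genes went both ways, 18 up and 10 down of 32: BBX24 (2.77 ± 0.07), BBX25 (1.52 ± 0.07), PIF4 (3.44 ± 0.20) and PIF7 (2.11 ± 0.11) rose and PAR1 (-2.07 ± 0.20) fell. For HY5 the estimate was 0.16 ± 0.09 (adjusted p = 0.165), and it was not called.

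By camera with a preset correlation of 0.01, 7 of the 18 lists moved, 6 up and 1 down. The adjusted p was 9.9e-33 for flavonoid synthesis, 5.1e-25 for the dark and sugar-starvation list, 1.2e-18 for the antenna, 1.7e-10 for photoprotection, 4.4e-11 for ribosome biogenesis, 4.8e-05 for heat shock and 0.000453 for light signalling. With the correlation between members estimated from these 6 libraries, photoprotection alone still passed (adjusted p = 0.0415 with an estimated correlation). The others then gave adjusted p = 0.0664 with an estimated correlation for flavonoid synthesis, 0.0537 for the dark and sugar-starvation list, 0.157 for the antenna, 0.294 for ribosome biogenesis, 0.0926 for heat shock and 0.392 for light signalling. By fry the 7 lists passed too, with 4 more: carbon fixation (adjusted p = 0.791 with an estimated correlation), nitrogen assimilation (0.294), other splicing regulators (0.807) and the reference genes (0.791). Fry asks if the members of a list changed in a direction, while camera asks if they changed more than other genes. With 56.3% of all tested genes called, passing fry says less. The member counts do not rest on these tests. Adjusted over the list alone, the number of called members was the same in 17 lists, and in the root markers it was 3 instead of 7.

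**Figure D1:**
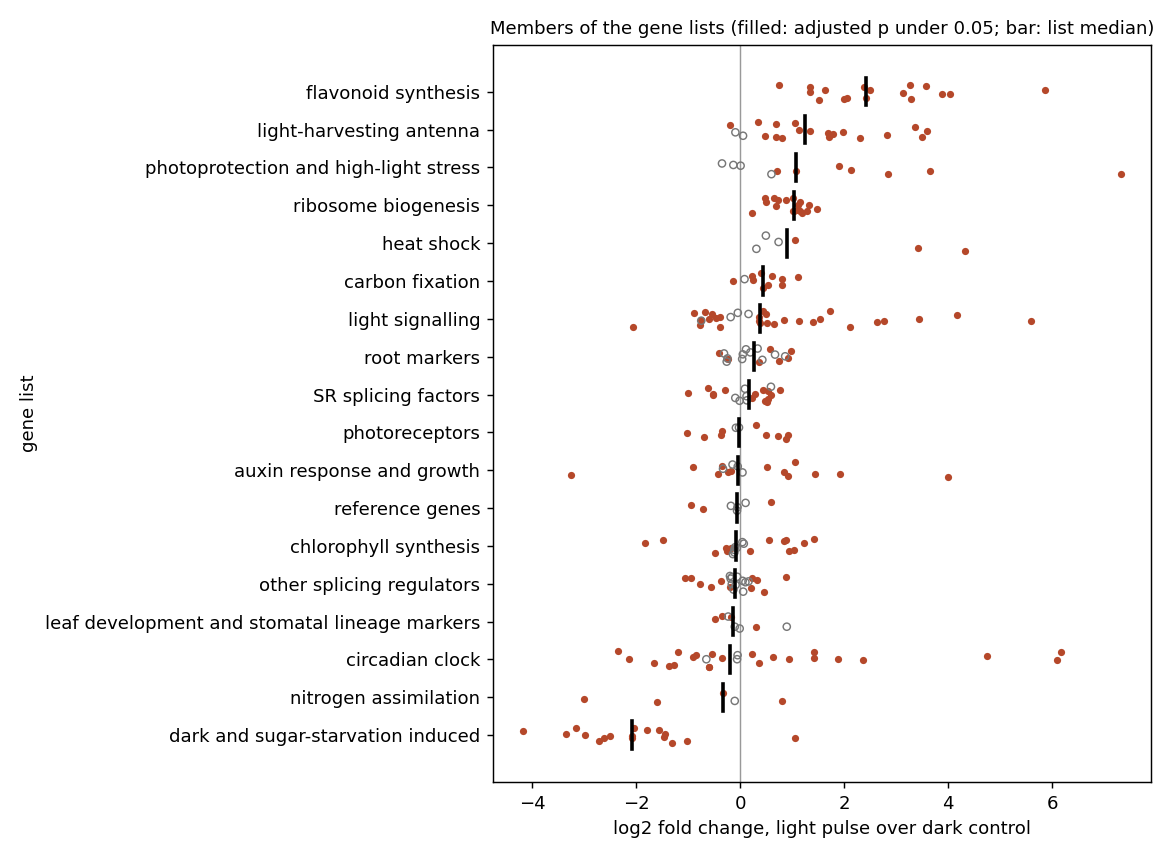
Change of each measured member of the 18 gene lists, light relative to dark. All 17 flavonoid genes and all 18 ribosome biogenesis genes rose, and 16 of 17 genes of the dark and sugar-starvation list fell.

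The clock genes split into strong rises and strong falls. Beside GI and LNK1, PRR7 rose by 4.75 ± 0.18, PRR9 by 2.36 ± 0.32, LNK2 by 1.88 ± 0.08 and CCA1 by 1.41 ± 0.07 (52.1 CPM in the dark). RVE2 fell from 825 CPM (-2.35 ± 0.06), TOC1 from 91.7 CPM (-1.28 ± 0.07), and PRR5 changed by -1.20 ± 0.12. LHY, the close relative of CCA1, was not called (-0.06 ± 0.07, adjusted p = 0.468), although without normalization it was, at -0.20 (adjusted p = 0.0187). In all, 11 of 26 clock genes rose and 12 fell (9 and 14 without normalization), and as a list they did not move (adjusted p = 0.728).

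**Figure D2:**
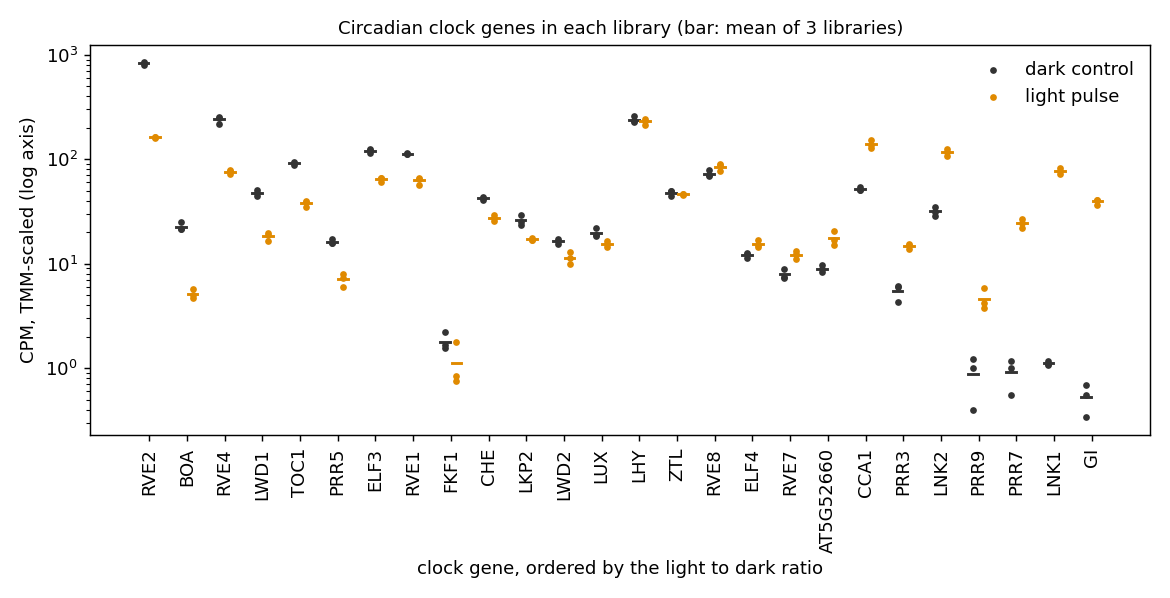
Level of the 26 clock genes in each of the 6 libraries. GI rose from 0.528 to 39.4 CPM and RVE2 changed by -2.35 on the log2 scale, while LHY was not called (-0.06).

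Other lists did not move by camera at the preset correlation. Nitrate reductase genes NIA1 (7.99-fold) and NIA2 (-1.60 ± 0.10) and the nitrite reductase gene NIR1 (-0.33 ± 0.06) fell while the transporter gene NRT1.1 rose (0.80 ± 0.08). As a list, nitrogen assimilation did not pass (adjusted p = 0.0969), but did without light library B (0.0174) or the 2 libraries richest in rRNA (0.0329). With an estimated correlation its adjusted p was 0.294. Carbon fixation genes rose in 9 of 11 cases, RCA by 1.11 ± 0.05, SBPASE by 0.80 ± 0.06, RBCS2B by 0.80 ± 0.06 and RBCS3B by 0.61 ± 0.06 (near-identical copies, so uncertain). This list missed the threshold (adjusted p = 0.0589) and passed without light library A (0.0239) or B (0.0448) or the 2 libraries richest in rRNA (0.00227), while its adjusted p = 0.791 with an estimated correlation. Among chlorophyll synthesis genes CHLH (1.43 ± 0.06), CAO (1.23 ± 0.06) and GUN4 (1.04 ± 0.05) rose and PORB (-1.48 ± 0.06) fell, 8 up and 7 down of 22 (7 and 12 without normalization). PHYA (-1.03 ± 0.06) and CRY2 (-0.71 ± 0.06) fell while PHOT2 (0.91 ± 0.07) and CRY3 (0.89 ± 0.07) rose, in all 5 up and 4 down of 11 photoreceptor genes (4 and 5 without normalization). In the auxin list IAA29 (-3.25 ± 0.20) and PIN3 (-0.43 ± 0.06) fell and IAA1 (1.44 ± 0.12) and IAA3 (1.06 ± 0.07) rose.

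Of 20 SR splicing factor genes 14 changed in level, in both directions, and no called member of the 2 splicing lists changed by more than 2.08-fold (U2AF35B). SR45a (0.77 ± 0.08) and RSZ22 (0.53 ± 0.06) rose, SR34b (-1.01 ± 0.10) and RS40 (-0.61 ± 0.06) fell, in all 9 up and 5 down (7 and 6 without normalization). RS31 fell by 0.30 on the log2 scale, a call lost without dark library A (adjusted p = 0.0545) or light library B (0.0509). SR30 rose by 0.28 ± 0.08, a call lost without normalization (adjusted p = 0.214) and without the 2 libraries richest in rRNA (0.0909). Among other splicing regulators the U2 factor genes U2AF35B (-1.06 ± 0.06), U2AF35A (-0.95 ± 0.06) and U2AF65A (-0.38 ± 0.07) and SKIP (-0.77 ± 0.06) fell and GRP8 rose (0.88 ± 0.06), in all 5 up and 6 down of 22 (3 and 12 without normalization).

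Seedlings were pooled whole, and camera found no common shift of the root markers (adjusted p = 0.774), the leaf and stomatal markers (0.728) or the reference genes (0.438), although fry called the reference genes lower (adjusted p = 0.00163). The root markers SCR (0.37 ± 0.06) and COBL9 (0.92 ± 0.25) rose and PHO1 (-0.41 ± 0.07) fell. EXPA7 was called at 0.74 ± 0.26, and lost the call without dark library A (adjusted p = 0.116) or C (0.0670) or light library A (0.0946) or B (0.0730). Of the leaf and stomatal markers AS1 rose (0.31 ± 0.06), and FIL (-0.35 ± 0.07) and FAMA (-0.48 ± 0.10) fell. YAB3 was called at -0.17 ± 0.07, and lost the call on leaving out any library but dark C, the adjusted p reaching 0.146. Of 7 usual reference genes 4 were not called, while ACT8 (-0.95 ± 0.06) and ACT2 (-0.72 ± 0.06) fell and the elongation factor gene AT5G60390 rose (0.58 ± 0.07). Without normalization 1 reference gene was called higher and 4 lower. The root markers then gave 3 higher and 4 lower, against 5 and 2 with TMM. For the leaf and stomatal markers the counts were 1 and 4, against 1 and 3.

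Splicing changed in far fewer genes than expression, and SR splicing factors stand out among them. In SR30 the part of the transcript between its alternative 3' splice sites (chromosome 1, 2943227 to 2943564) held 25.2 ± 1.26% of the gene's counts in the dark and 12.0 ± 0.45% in light (log2 -1.08 ± 0.09, adjusted p = 8.9e-08). Junction reads that include this part fell from 73.0 ± 6.74% to 27.6 ± 3.07% of those at its borders. In SR34a a skipped exon (chromosome 3, 18332248 to 18332492) went from 8.43 ± 1.24% to 3.43 ± 1.02% (-1.33 ± 0.20, adjusted p = 0.000665), with junction inclusion falling from 16.9% to 5.27%. RS2Z33 lost a stretch next to an alternative 3' splice site (chromosome 2, 15671601 to 15671818), from 5.24 ± 0.40% to 2.62 ± 0.20% (adjusted p = 0.00411), and its junction inclusion went from 15.3% to 3.97%.

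RS41 carries 2 adjoining parts with lower usage, at 21131562 to 21131815 (-0.90 ± 0.17, 6.40% to 3.47%) and 21131816 to 21131887 (-1.19 ± 0.25, 3.21% to 1.42%) of chromosome 5. The first was lost without dark library C (adjusted p = 0.0515) or light library A (0.0623), the second without dark library B (0.0823) or C (0.0681) or light library B (0.113). Both were lost without the 2 libraries richest in rRNA (0.194 and 0.174), and the second with DESeq2 (0.113). The RS2Z33 call was lost with DESeq2 (adjusted p = 0.0679) and without the 2 libraries richest in rRNA (0.0701), and those of SR30 and SR34a held under every alternative run. A retained intron of SC35 was also called (0.78), which is mentioned after its value was seen and outside the naming rule. In total 5 of the 14 SR genes with a tested part carried a call, and 0 of the 10 other splicing regulator genes by edgeR or DESeq2 (2 of their 19 parts at an unadjusted p under 0.05). Set against the remaining genes, splicing regulators of both lists carried calls more often, 5 of 24 genes against 32 of 2453 (odds ratio 19.8, 95% interval 5.44 to 59.5, Fisher's exact p = 1.9e-05, genes treated as independent).

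**Figure D3:**
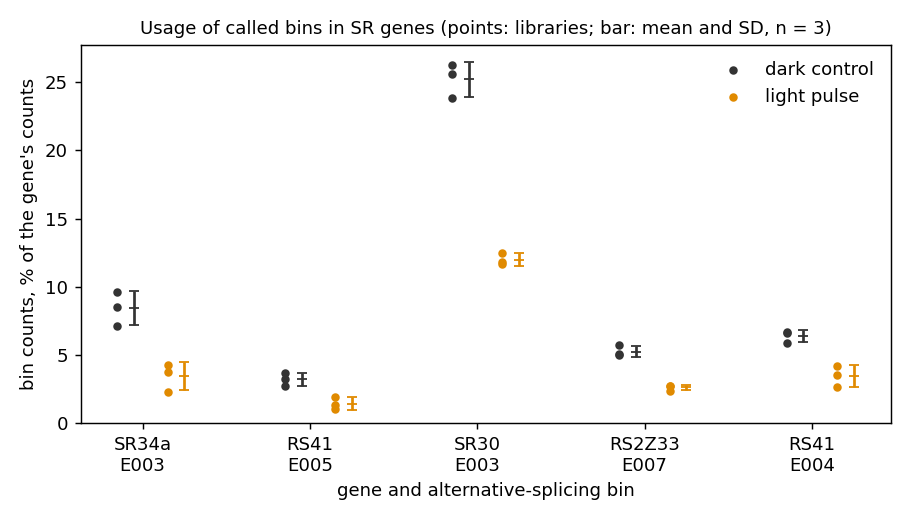
Share of the gene's counts in 5 alternatively spliced parts of SR genes, in each library. In SR30 it went from 25.2% to 12.0% and in SR34a from 8.43% to 3.43%.

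Outside the SR genes, the clock gene RVE8 gained a short stretch at an alternative 3' splice site (chromosome 3, 2948156 to 2948177), from 13.7 counts on average in the dark to 37.7 in light, 4.28 ± 0.70% of the gene (log2 1.52 ± 0.23, adjusted p = 0.000768). Junction reads that include it were 0% of those at its borders in the dark and 30.6 ± 3.60% in light, although RVE8 expression rose by just 0.23 ± 0.07. In RCA, a part of 11 bases moved from 55.5 ± 0.17% to 46.6 ± 0.55% junction inclusion (usage log2 -0.21 ± 0.03, adjusted p = 0.00143). SAG21 showed higher use of a part of 4 bases (3.41 ± 0.48), with 34 counts on average in the dark and 6.33 in light, while the gene's own counts collapsed, and its junction inclusion of 0.0446% and 0.271% was not apart (exact p = 1). These 3 calls held in every alternative without a minimum fold. FBA2 (1.52 ± 0.26) was lost without the 2 libraries richest in rRNA (adjusted p = 0.0565), and 0% of its junction reads entered the part in either group.

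The remaining named parts lost their calls on leaving out 1 or more single libraries. Fewer libraries also weaken the test, so a lost call does not show that the change rests on the library left out. The estimates kept their sign in every setting, with 0.44 to 0.62 for DRM1. Higher use was called in CA2 (1.36 ± 0.29), NAP1;1 (0.675% to 1.48% of counts), AT2G01100 (1.09 ± 0.22), DRM1 (0.53 ± 0.12) and a second part of RCA (0.42 ± 0.08). Lower use was called in BGLU11 (-1.28 ± 0.26 and -1.14 ± 0.24), AT1G73350 (-1.28 ± 0.26) and AT5G16980 (-1.23 ± 0.27). Leaving out light library B ended the calls of CA2 (adjusted p = 0.116 without it), NAP1;1 (0.116), AT2G01100 (0.123), DRM1 (0.118), AT5G16980 (0.179) and the second part of BGLU11 (0.113). The first part of BGLU11 was lost without light library C (0.0775), the second part of RCA without dark library C (0.106), and AT1G73350 without dark library B (0.0547) or light library A (0.0649). DRM1 was lost without any 1 of the 6 libraries, CA2 without any but light A, NAP1;1 without any but dark A, AT5G16980 also without dark B, dark C or light A, AT2G01100 also without dark B, and the second BGLU11 part also without dark C or light A.

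In all, 3348 alternatively spliced parts in 2477 genes were tested and 40 (1.19%) in 37 genes were called, 18 with higher and 22 with lower usage in light, against 303 at an unadjusted p under 0.05. Of the 40, 2 share coordinates with another gene, and 1 more, in RWA3, lies in a gene with a called overlapping exon part. That leaves 37 parts, 16 higher and 21 lower. The events of all 40 were 8 alternative 3' sites (2 higher, 6 lower), 5 alternative 5' sites (3 and 2), 2 skipped exons (0 and 2), 9 retained introns (6 and 3) and 16 of mixed kind (7 and 9). Leaving out the retained introns, 27 of the 31 called parts had at least 10 junction reads in each group. In 10 of them, among these RCA's second part, FBA2, GOX1 and AT2G01100, junction inclusion was 0% or 100% in both groups. Inclusion could therefore not show a shift in these 10, and it speaks neither for nor against their calls. In 17 it moved the same way as the counts of the part, with light and dark apart in 13. AT5G16980, with fewer reads, moved the other way (2.78 percentage points). Junction reads that enter a part also fall on it, so this is not a separate measure. Retained introns did not favour a direction (exact binomial p = 0.508, events treated as independent). Of the 37 genes, 19 rose, 8 fell and 10 were not called in expression. Genes called in expression carried a splicing call in 1.61% of cases and others in 1.25% (odds ratio 1.29, 95% interval 0.602 to 3.00, Fisher's exact p = 0.596), so no association was found.

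Introns gave more calls than annotated events. Among called introns with at least 20 counts in the higher group, outside loci that the file marks as overlapping, BOU gained the most. Its second intron (chromosome 5, 18989813 to 18990494) held 0.0561 ± 0.05% of the gene's counts in the dark and 1.48 ± 0.25% in light (log2 4.48 ± 0.51, adjusted p = 0.000882). The second intron of AT1G58602, 4420 bases long, rose from 0.509 ± 0.13% to 9.85 ± 1.63% (4.26 ± 0.21) while the gene itself fell (-0.79). The third intron of RCA rose (3.60 ± 0.64), with single counts of 13, 5 and 15 in the dark and 387, 324 and 40 in light. It was lost without the 2 libraries richest in rRNA (adjusted p = 0.117).

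Lower intron usage was found in the first intron of AT-HSFC1 (-2.54 ± 0.40), which lies within the coordinates of another gene, AT3G24518, and was lost without the 2 libraries richest in rRNA (adjusted p = 0.0662). The first intron of the splicing protein gene U2B'' went from 24 counts on average in the dark to 3.33 in light (-2.21 ± 0.35). AT3G05160 lost usage of an intron (-2.46 ± 0.50), a call that ended without dark library B (adjusted p = 0.0703) or light library B (0.0785). Of 3321 introns tested, 204 in 177 genes were called, 131 higher and 73 lower, 28 of them sharing coordinates with another gene. Introns as a whole took 1.54 ± 0.04% of intron and exon counts in the dark and 1.44 ± 0.03% in light, a difference of -0.102 percentage points (exact permutation p = 0.1, the smallest that 3 against 3 libraries can give).

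Among exon parts outside the splicing set, the 6 named calls all lie where 2 genes overlap, and all 6 carry the unexplained event name "extreme". A part of ATMYOS1 (chromosome 5, 22039383 to 22039388) rose from 11.7 ± 0.53% to 51.0 ± 4.00% of the gene's counts (2.13 ± 0.08), and this stretch lies within LHCB3, which rose by 2.81. A part of VPS22 rose (1.83 ± 0.15) inside FAD4, itself up by 1.56, and one of HGO rose (1.68 ± 0.17) where AT5G54090 overlaps it and HGO expression changed by -1.60. One of PKT1 went from 39.6 ± 5.66% to 4.75 ± 0.72% (-3.01 ± 0.16) inside LSM5 (0.46), while PKT1 itself rose by 3.11. AT5G42760 behaved alike, 32.6 ± 5.29% to 4.31 ± 0.29% (-2.89 ± 0.17), with the gene up by 3.00 and its neighbour AT5G42765 near constant (-0.02). KELP, called at -3.10 ± 0.44, sits inside AT4G10910 (-3.27) and lost the call without any 1 of the 6 libraries (adjusted p up to 0.179).

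Of 102199 exon parts tested, 101 in 61 genes were called, 41 higher and 60 lower. The 35 that share coordinates with another gene all moved toward that neighbour's change relative to the gene they were assigned to, so they are not counted here as splicing changes. Direction alone was compared. In ATRZ-1A the part changed by -0.92 although the gene and its neighbour rose alike (0.48 each), so the neighbour's reads do not account for the size of every such change. Of the 66 others, 26 lie in genes whose count holds such a called overlapping part, among them RPL18AA, RWA3 and ATMYOS1, so their usage can move with the neighbour's reads. That leaves 40 called exon parts, 22 higher and 18 lower.

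Of the called junctions, 8 were read in one group and at 0 in the other, and these include some of the largest changes. An unannotated junction of TUB3 had 0 reads in the 3 dark libraries and 126, 117 and 102 in light, 2.94 ± 0.32% of the gene's counts (adjusted p = 2.7e-17). It joins TUB3 to the neighbouring and nearly identical TUB2, so it is uncertain where these reads belong. GLN2 showed the same at positions 13831348 to 13831447 of chromosome 5, 0 reads in the dark and 126, 103 and 94 in light (0.424 ± 0.07%, adjusted p = 7.4e-17), while the expression of the gene was not called (-0.11, adjusted p = 0.108). A junction in ATGRP-3 (chromosome 2, 2026610 to 2026734) had 38, 34 and 37 reads in the dark and 0 in light (adjusted p = 6.0e-09). An annotated junction of AT1G63830 (chromosome 1, 23686693 to 23686787) went from 12.3 ± 1.79% to 0.617 ± 1.07% (-4.08 ± 0.52, adjusted p = 1.5e-05). Its light counts were 0, 3 and 0, so the size of the change rests on light library B, without which the light group had no reads.

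RBCS1A and RVE2 were called on weaker grounds. The RBCS1A junction had 0, 11 and 0 reads in the dark and 0, 1633 and 939 in light, so it is absent from light library A, and DESeq2 did not call it (adjusted p = 1). The RVE2 junction had 25, 21 and 22 reads in the dark and 0 in light where the gene fell as well, and lost its call without any 1 of the 6 libraries (adjusted p up to 0.313). Of 65821 junctions tested, 111 in 72 genes were called, 48 higher and 63 lower in light, 44 of them unannotated and 44 sharing coordinates with another gene. A further 15 lie in genes with a called overlapping exon part. On simulated data the false share among junction calls was above the adjusted threshold, so more of the 111 may be false than the threshold implies. With counts scaled to the mean gene level instead of the offset, 101 were called, 56 higher and 45 lower, so the direction of the junction calls as a set is not settled.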

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

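Requiring a fold left fewer changed genes, 5480 at 1.5-fold and 2309 at 2-fold. The other gene settings, no normalization, RLE, DESeq2, filters, nuclear genes and rRNA left out, gave 9716 to 11579, and leaving out 1 library each gave 10366 to 11018. Splicing calls depended more on the library set. The 40 parts became 11 with DESeq2, 21 to 36 without 1 library (dark B, dark C and light B move the count most) and 16 without the 2 libraries richest in rRNA. Settings with fewer libraries test with less power. Leaving out the rRNA-rich pair leaves 2 libraries in each group, and no other pair was tried. The falls in calls under it cannot be put down to rRNA. The 204 introns became 125 at a mean of 20 counts, 51 with DESeq2, 93 to 134 without 1 library (any of dark A, dark B, dark C, light A, light B and light C) and 41 without the rRNA-rich pair. The 101 exon parts became 61 without shared coordinates, 51 to 80 without 1 library (dark B, dark C, light A and light B most) and 23 without the pair. The 111 junctions became 45 with DESeq2, 67 without shared coordinates, 69 among annotated junctions and 86 to 120 without 1 library.

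Of the 18 lists, 7 moved in the main test, 1 passed with an estimated correlation, 11 passed by fry, and 7 to 9 without 1 library. The list direction turned, without ever passing, for the clock without dark library C (adjusted p = 0.969, the highest of 0.419 to 0.969 without 1 library) and without the rRNA-rich pair (0.937), and for photoreceptors without normalization (0.975) and without the pair (0.983). The odds ratio of expression and splicing calls fell to 0.923 within quartiles of expression (exact Mantel-Haenszel p = 0.848), and was 1.72 to 2.62 without 1 library. For splicing regulators the exact p stayed at 0.000731 or below without 1 library, and was 0.00963, with 2 regulator genes instead of 5, without the pair. The share of retained introns with higher usage, 66.7%, became 50% at a mean of 20 counts, 40% with scaled counts, 25% to 70% without 1 library (33.3% without dark C, 25% without light B) and 33.3% without the pair. The intron share difference stayed between -0.126 and -0.0839 percentage points without 1 library.

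For 90 named genes 1376 of 1436 values kept direction and call, 59 lost the call, 1 gained it and 0 changed sign. For 18 named parts 221 of 281 kept it, and 84 of the 88 called genes but 5 of the 18 parts kept it in every setting without a minimum fold. No paired analysis was possible because the columns carry letters that no source ties to the replicate numbers in the labels' titles. Deviations from the group mean correlated at -0.067, 0.12 and -0.0405 between same-letter libraries of the 2 groups (A, B and C). They correlated at 0.129 between dark C and light A, the libraries richest in rRNA, and at 0.0961 between dark A and light C. All other dark and light pairs were negative. A pairing other than by letter is thus not excluded, and no block by one was run. A block by letter called 11595 genes, 32 parts, 177 introns, 75 exon parts, 106 junctions and 8 lists. The settings on rRNA counts, on shared coordinates, on annotated junctions, on junctions at 0, the block by letter and RLE for the lists were added after the data had been seen.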

Other observations

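Chaperone families outside the lists rose together. All 7 HSP90 genes picked out by symbol rose (median 2.07), HSP81-3 by 2.43 and AtHsp90-1 by 2.22. The 6 HSP70 genes picked out by symbol outside the heat-shock list all rose too (median 1.69), Hsp70-2 by 2.65 and HSC70-5 by 1.90. Members under other symbols may be missing. The cytosolic HSP90 copies are nearly identical, so the split among them is uncertain. Of 11 FTSH protease genes 8 rose and 0 fell, ftsh9 by 1.25 and FTSH8 by 1.04. Sugar transporter genes of the STP family went the other way, 5 of 6 down, with STP1 at -2.08 and AtSTP14 at -1.52. Fasciclin-like FLA genes rose in 11 of 14 cases. Without normalization the counts were 7 of 7, 6 of 6, 8 of 11, 5 of 6 and 9 of 14 in the same order.

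These families were formed from gene symbols after the data had been seen. Symbols can also join unrelated genes, such as CHLG and EBP1 within the ATG set, so the count of moved families is approximate. Of 47 families 9 moved at the preset correlation (adjusted p = 4.7e-12 for HSP90, 3.6e-09 for HSP70, 0.00609 for FTSH, 0.00932 for STP and 0.00212 for FLA), and 0 of 47 with an estimated correlation (0.299 for HSP90).

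In the part that follows, the tests of skipping junction reads in SR genes, of all explanations of the intron pattern and of both explanations of the junction pattern were chosen after the results were seen. The test of read depth in SR genes and the counts over splits were written before.

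The SR genes carried 5 of the 37 genes with a splicing call. More reads on SR genes do not account for it: within quintiles of the best-covered part the odds ratio for the SR list was 39.9 (95% interval 9.42 to 153.5, exact Mantel-Haenszel p = 1.8e-06). Reads that leap over a part do not fall on it, and relative to gene counts they rose in light in 5 of 5 measurable SR parts (the 2 of RS41 share theirs). Light and dark were apart in 1, SR30, at 2.32 ± 0.89% and 6.17 ± 0.25%. For the other parts these reads leave a light effect on splicing and chance open, and they cannot be told apart with 3 libraries in each group. Reads shared between SR paralogs were not tested and stay open.

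More introns gained usage than lost it, 131 against 73, while introns as a whole took a smaller share of counts in light. A constant background such as genomic DNA would make intron usage fall as a gene rises, with a slope near -1, and over 3532 genes the slope was -0.0339 ± 0.0113. With each gene's weight held at its dark mean over 16259 genes the share was higher in light by 0.168 percentage points (larger group SD 0.0399, exact p = 0.1). As counted over the same genes the difference was -0.013 (exact permutation p = 0.7), so a change in which genes supply the reads could hide a rise within these genes. These shares are relative to gene counts and leave out introns with shared coordinates and genes without a count in every library. For all introns relative to gene counts the difference was -0.134. Most of the fall was thus lost with the choice of introns and genes, and gene weights are not shown to account for it. The median intron usage per gene was higher in light by 0.10 on the log2 scale, at least 0.08 in each light library against at most 0.02 in a dark one. With 10 splits of 6 libraries, greater retention in light and chance cannot be told apart.

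Unannotated junctions were often at 0 in 1 library and well covered in another of the same group, as for RBCS1A, a pattern seen in 3 of the 44 called ones. At matched read counts it held for 31.9% of 939 unannotated junctions, against 1.09% of annotated ones, a ratio of 29.4. This is consistent with discovery of unannotated junctions separately in each library, so that a 0 may mean not searched. Of 348 unannotated junctions with a library at 0 and another at 20 or more, 11 (3.16%) split by light and dark. The 348 include the 300 that are all or none within a group, and those cannot split by group. A low share was thus fixed by the selection, and it does not decide on light-dependent use. TUB3, GLN2 and ATGRP-3 are among those that do split by group, and for them neither reading was tested alone.

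The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 11353 genes and the highest other 0, 40 alternatively spliced parts against 2, 204 introns against 3, 101 exon parts against 1, 111 junctions against 13 and 5 splicing regulator genes with a splicing call against 0, each with 1 of the 10 splits as large, the real one. Every other split mixes light and dark libraries in both groups, so the difference between light and dark enters the spread within groups and lowers the calls. The counts of the other splits are therefore no measure of false calls. For the lists, 3 of the 10 splits moved 7 or more, the real one with 7 and the highest other with 9, so the real count of moved lists is not the highest.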
